A study of Mus musculus with 12 samples.

How the data were processed

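The study measured transcripts in dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, of male C57BL/6J mice aged 6 to 12 weeks. Per the labels' protocols, lumbar ganglia L1 to L6 were frozen after the mice were killed at zeitgeber time (ZT) 2, 8, 14 or 20, where ZT is the hour counted from lights on. RNA was extracted with an RNeasy kit, messenger RNA was enriched with oligo(dT) beads, fragmented and copied with random primers, and the libraries were sequenced as paired reads of 150 bases on a DNA nanoball platform. The kit's handling of strand is not given in the sources used here, and neither are the hours of light, so reads of overlapping genes on opposite strands may not be told apart. There were 12 libraries, 3 at each of the 4 times, numbered as replicates in the labels. The labels do not say that each library came from a separate animal, and p-values then measure only the spread between these libraries, which may be partly technical. The library numbers of the labels follow the order of the time points (3 to 5, 6 to 8, 11 to 13 and 16 to 18), so any batch of collection or library preparation cannot be told apart from time of day.

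Per the submitters' processing notes, HISAT2 2.2.1 and StringTie 2.1.5 were used with mouse genome build GRCm38.p6; their roles, the annotation release and the step that made the gene table are not given in the sources used here. The deposited table holds estimated counts per gene that are not whole numbers, for 38942 rows, of which 38594 carry versioned Ensembl gene IDs and 348 carry IDs of loci that StringTie assembled. The values are on a coverage scale: in each library the most frequent value above 10, between 16.4 and 17.2, was shared by genes whose lengths differed several fold, as when a coverage of 1 gives the same value whatever the gene's length. The totals of 89.8 to 125.0 per library, in units of 1000000 counts, are therefore not read numbers, and the exact read depth is unknown. From the genes' median transcript lengths it was approximated as 47.9 to 67.1 in the same unit. Because the values are inflated relative to reads and differently so for short and long genes, counting error is not modelled exactly, and a table of approximate reads was tested as an alternative. Values were rounded to whole numbers before the count tests.

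Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38. Of the 38594 Ensembl IDs, 38462 matched it without the version suffix and 37795 with it. Where a symbol stood on several IDs (79 symbols), it was kept for the ID of the highest total. The 348 assembled loci, 0.203% to 0.231% of each library's total, were left out of the library sizes and tests. Transcripts of the mitochondrial chromosome took 10.3% to 11.6% of a library, and nuclear pseudogenes of mitochondrial origin, which share reads with them, took 4.87% to 5.43%. Members of the haemoglobin gene pairs are near-identical copies, so the split of reads within a pair is uncertain.

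The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9; filterByExpr on the 4 groups, TMM normalization, robust fit, 1 model with the 4 times over all 12 libraries, no covariate). It was applied to 25809 genes, of which 16666 are protein-coding; 12785 genes fell below the filter. From this fit came a test of any difference between the times (3 degrees of freedom), a test of a 24-h cosine and sine pair, a test of the remaining 12-h alternation (ZT2 and ZT14 against ZT8 and ZT20), and the 6 contrasts between pairs of times. Every adjusted p is a Benjamini-Hochberg value, with 0.05 as the threshold, and is from edgeR unless another tool is named. The amplitude of a gene is that of its fitted 24-h cosine on the log2 scale, which is the log2 distance from the mean level to the peak, and the peak time is where that cosine is highest; with sampling every 6 h both are estimates from 4 points. Levels are CPM, counts scaled by the TMM-normalized library size, given as mean ± SD over 3 libraries.

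Before the data were examined, 39 gene lists were fixed: the clock's repressor and output arm, the clock's activator arm, clock outputs of many tissues, glucocorticoid-responsive genes, heat shock, cold-inducible RNA-binding proteins, the unfolded protein response, immediate early genes, 12 lists of neuronal and pain-related genes, markers of satellite glia, myelinating Schwann cells, macrophages, T and B cells, neutrophils and bone marrow, erythroid cells, fibroblasts, endothelium, smooth muscle and pericytes, skeletal muscle, adipocytes, bone and cartilage, and spinal cord, and lists for cholesterol synthesis, interferon-stimulated genes, cell cycle, respiratory chain, ribosomal proteins and mitochondrially encoded genes. They were tested for ZT14 against ZT2 and for ZT20 against ZT8 with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 39 lists of a contrast. A list score is the mean log2 CPM of its measured members in a library. The list called the activator arm also holds genes placed there as in phase with it, Cry1 among them. Members were also counted past the gene tests, over all genes and adjusted over the list alone.

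The genes named in the text follow a rule also fixed before the data were examined: every measured member of both clock lists; the 12 genes of lowest p past the 24-h test outside them; for the 2 contrasts of opposite times the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean CPM of 1 or more and no overlap between groups; the top 3 each way for the contrasts of adjacent times; the 3 members of lowest any-time p of each list, whether or not past the threshold; and Scn9a, Scn10a, Scn11a, Trpv1, Trpa1, Calca, Tac1 and P2rx3 always. Some genes that the rule covers are not reported here. In the parts that rank called genes, predicted genes, clone-named genes and pseudogenes were to be passed over, and none of the called genes in the contrasts was. A gene named outside the rule is said to have been chosen after its values were seen.

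The alternatives planned were RLE size factors, DESeq2 1.42.0, no filter on low counts, a filter of CPM 1 in 6 libraries, the table without haemoglobin, mitochondrially encoded and skeletal muscle genes, the replicate number as a block, 1 surrogate variable from sva 3.50.0, each library left out in turn, and for the pairwise contrasts a fit on the 6 libraries compared. Chosen after seeing the data were approximate reads, limma-trend, protein-coding genes only, the fit without the library of highest skeletal muscle score at each time, that score as a covariate, and the table with the assembled loci. The libraries were also regrouped at random 99 times for the tests over all times, and in all 10 ways for each pair of times. The methods were tested on simulated data drawn from the libraries' own means, sizes and dispersions, with 200 genes raised or lowered at ZT14. The counts were drawn in a single run, independently for each gene, with dispersions that edgeR had estimated, so a comparison of tools may favour edgeR. For the simulated ZT14 against ZT2 comparison, run on 24873 genes, edgeR recovered 26.9% of the genes changed 1.5-fold, 56.7% of those changed 2-fold and 68.2% of those changed 3-fold, and 2.88% of its 104 calls were false. DESeq2 made 176 calls in the same simulation, of which 29.5% were false. Libraries of 1 time differed beyond counting noise in all 12 pairs (chi-square per gene of 9.84 to 27.0 on the approximate reads), so no library was counted as a copy of another.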

Results

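Polyadenylated RNA of lumbar DRG from male mice was profiled at ZT2, ZT8, ZT14 and ZT20, with 3 libraries at each time. The title of the series names clock genes of nociceptors, the neurons that sense painful stimuli, together with excitability and pain; the comparison asks which ganglion transcripts differ with the time of day. In units of 1000000, the estimated counts of a library summed to 91.7, 99.5 and 104.2 at ZT2, to 102.9, 89.8 and 104.8 at ZT8, to 101.5, 105.0 and 107.1 at ZT14, and to 100.4, 110.5 and 125.0 at ZT20. Between 28413 and 29355 genes had a value of 1 or more in a library. Log2 CPM of any 2 libraries correlated across genes with a Pearson r of at least 0.965 and a median of 0.971, genes not being independent replicates. Normalization factors lay between 0.97 and 1.02. Markers of skeletal muscle, a tissue that borders the ganglia, differed strongly between libraries of the same time. The highest muscle scores were those of ZT2 replicate 2 (4.52 log2 CPM), ZT8 replicate 3 (4.70), ZT14 replicate 1 (4.93) and ZT20 replicate 1 (5.55), against 1.14 for ZT20 replicate 2.

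The molecular clock of the ganglia was the clearest signal of time of day. Arntl, which encodes the activator BMAL1 that drives the clock with CLOCK, was high at ZT20 and ZT2 and low at ZT8 and ZT14: its level was 6.24 ± 0.18 CPM at ZT2, 2.83 ± 0.36 at ZT8, 2.63 ± 0.14 at ZT14 and 6.39 ± 0.74 at ZT20 (SD, n = 3 each). Genes of the repressor and output arm ran against it. Nr1d1, a nuclear receptor that represses Arntl, peaked at ZT8 with 48.5 ± 8.81 CPM and was lowest at ZT20 with 13.3 ± 0.89 CPM. Dbp, a transcription factor driven directly by the clock, stood at 32.1 ± 4.72 CPM at ZT8 and 8.26 ± 0.82 CPM at ZT20. Per2, a period gene that feeds back on the activators, reached its highest level later, 8.30 ± 0.77 CPM at ZT14 against 3.80 ± 0.54 CPM at ZT20.

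In the edgeR test of a 24-h component, 8 of the 19 measured clock genes passed over all 25809 genes. Their fitted amplitudes on the log2 scale were 1.11 ± 0.12 (SE) for Dbp, 0.93 ± 0.09 for Nr1d1, 0.86 ± 0.06 for Arntl, 0.75 ± 0.07 for Ciart, 0.53 ± 0.05 for Per3, 0.51 ± 0.05 for Per2, 0.37 ± 0.04 for Nr1d2 and 0.20 ± 0.02 for Tef. Arntl peaked at 23.1 ± 0.25 h (SE). The repressor and output genes peaked between 8.0 h for Nr1d1 and 12.0 h for Per2, with Nr1d2, Ciart, Dbp, Per3 and Tef at 9.4, 9.8, 9.9, 10.7 and 10.8 h. Adjusted p-values of edgeR ran from 0.000399 for Arntl to 0.0366 for Tef. Adjusted over the list alone, 10 of the 12 members of the repressor and output arm passed, Hlf, Per1 and Bhlhe40 among them, against 7 over all genes. Of the 7 measured members of the list of the activator arm and genes in phase with it, 4 passed over the list alone (Arntl, Cry1, Npas2 and Nfil3) and 1 over all genes. For ZT14 against ZT2, 1 member was higher and 3 were lower over the list alone. Cry1, whose product represses the activators, had its highest level at ZT14 with 12.6 ± 0.46 CPM against 10.1 ± 0.11 CPM at ZT8 (edgeR adjusted p = 0.405 over all genes). Clock, Cry2, Bhlhe41 and Rora passed neither way; Clock had an amplitude of 0.07 ± 0.05. Clock list members made up 8 of the 17 genes past the 24-h test (two-sided Fisher's exact test, p = 3.75e-22). That test takes genes as independent, although all were measured in the same 12 libraries, so its p does not measure the spread between libraries.

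**Figure D1:**
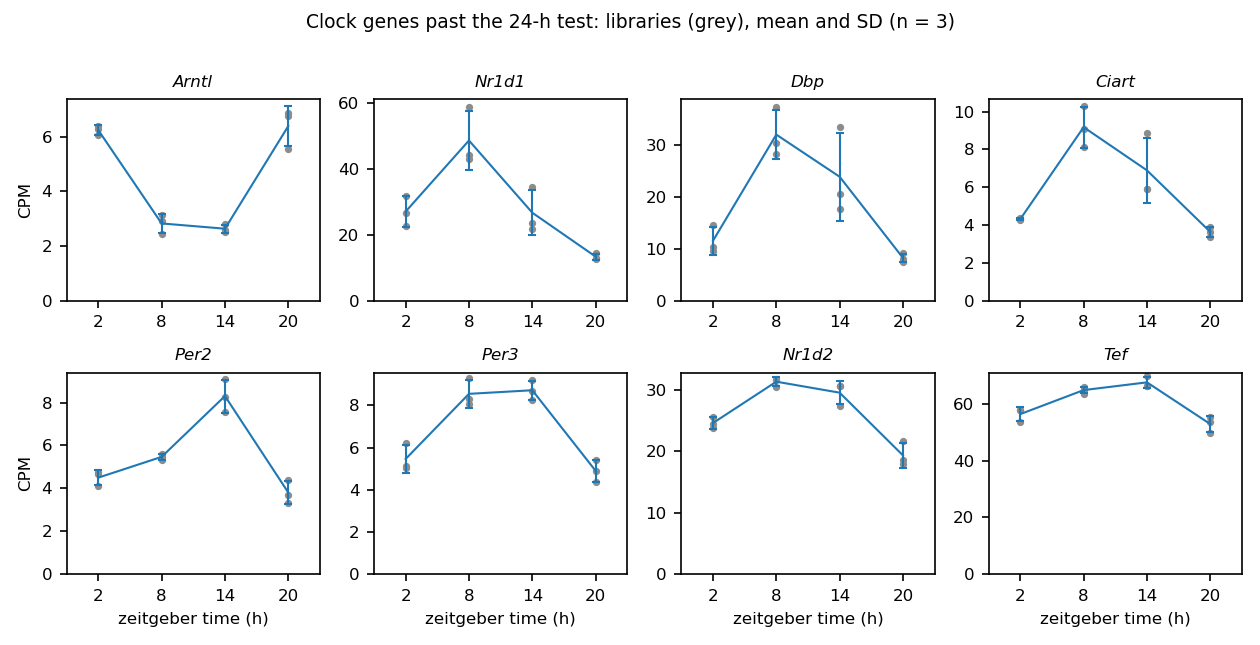
CPM (vertical axis, from 0) of the 8 clock genes past the 24-h test at each zeitgeber time (horizontal axis, h). Grey points are the 3 libraries of a time, the line joins their means and bars are SD; Arntl is high at ZT20 and ZT2 and the other 7 genes are highest at ZT8 or ZT14.

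Outside the clock lists, 9 genes passed the 24-h test. Fabp7, a fatty acid-binding protein of glia, had the lowest p of all genes (edgeR adjusted p = 6.4e-05) and a high level, 590.4 ± 33.1 CPM at ZT2, 322.1 ± 28.7 at ZT8, 220.7 ± 19.5 at ZT14 and 455.1 ± 20.5 at ZT20 (SD, n = 3 each). Its amplitude was 0.75 ± 0.04 and its peak fell at 0.71 ± 0.19 h (SE). Fmo2, a flavin-containing monooxygenase, ran the other way, from 6.43 ± 0.80 CPM at ZT2 to 17.8 ± 1.96 CPM at ZT14, with a peak at 13.5 h (adjusted p = 0.00415). Fam107a, an actin-associated gene known as stress- and glucocorticoid-responsive, also peaked at 13.5 h and Slco1a4, an organic anion transporter of barrier endothelium, at 12.2 h. Khk, the enzyme that opens fructose metabolism, was at 21.3 ± 1.92 CPM at ZT2 and between 33.5 and 36.2 CPM at the other times. Dbi, an acyl-CoA-binding protein, Sat1, a polyamine acetyltransferase, and Spg21 were lowest at ZT14, with amplitudes of 0.18, 0.21 and 0.25. Dock9, an exchange factor for small GTPases, declined from 33.9 ± 2.96 CPM at ZT2 to 21.2 ± 1.31 CPM at ZT20. Fabp7 lies on chromosome 10 at 57784881 to 57788450 (ENSMUSG00000019874.11), Fmo2 on chromosome 1 at 162874317 to 162898726 (ENSMUSG00000040170.13) and Arntl on chromosome 7 at 113207465 to 113314126 (ENSMUSG00000055116.8), all in GRCm38. The values are per gene, and the exons they cover are not given in the sources used here.

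Taking the 24-h test as a whole, 17 genes passed and 1342 had an unadjusted p under 0.05, where 1290.45 are expected by chance. Fabp7 passed in all 25 other settings, Arntl and Fmo2 in 24, Per3, Nr1d2 and Slco1a4 in 23, Ciart in 22, Nr1d1 in 21, Per2 in 18, Dbp in 17, Khk in 14, Dbi and Spg21 in 13, Sat1 in 12 and Tef, Dock9 and Fam107a in 11. In the 12 fits without 1 library, Tef lost its call in 12, Fam107a in 11, Dbi, Dock9, Sat1 and Spg21 in 10, Khk in 9 and Dbp in 7. Over the 25 settings the amplitude was 1.02 to 1.16 for Dbp, 0.84 to 0.97 for Nr1d1 and 0.18 to 0.21 for Tef. It was 0.28 to 0.37 for Khk, 0.43 to 0.52 for Fam107a and 0.18 to 0.24 for Sat1. Without the 4 libraries richest in muscle RNA, 4 genes passed. Leaving out 1 library gave 5 genes without ZT20 replicate 3, 8 without ZT20 replicate 2 or ZT2 replicate 1, 9 without ZT8 replicate 2, 10 without ZT2 replicate 2, ZT8 replicate 1 or ZT14 replicate 2, and 11 without ZT14 replicate 3 or ZT20 replicate 1.

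**Figure D2:**
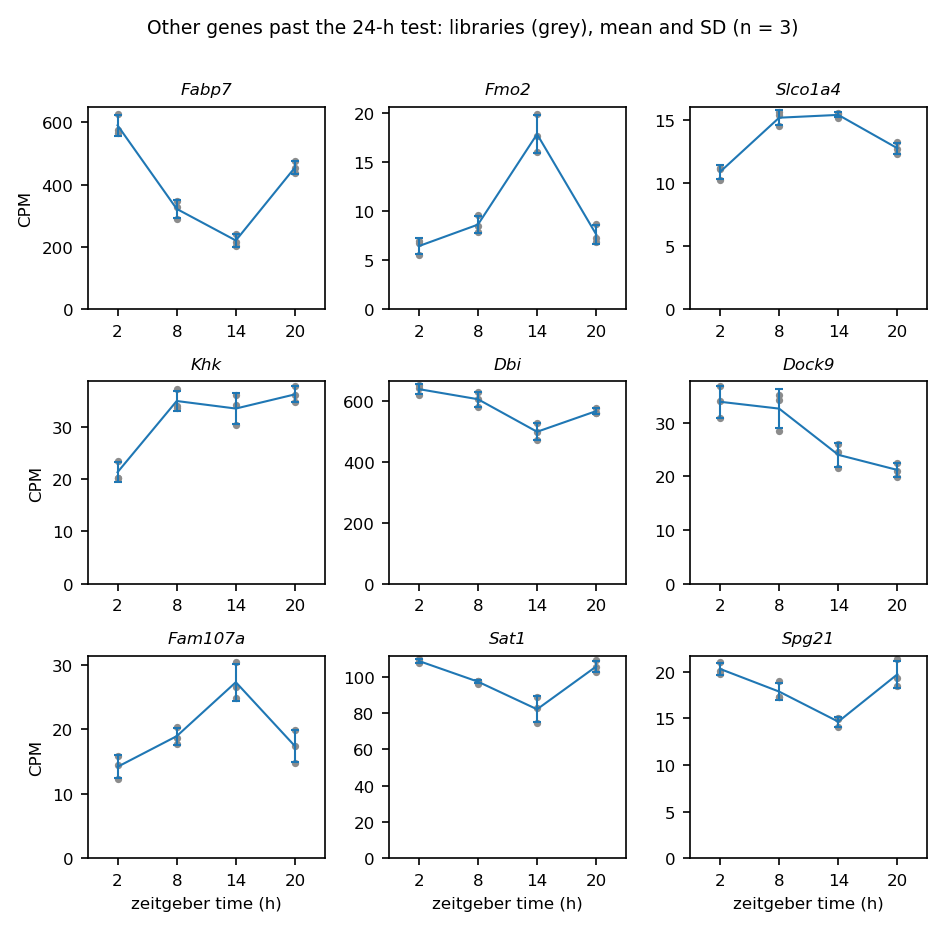
CPM (vertical axes, from 0) of the 9 other genes past the 24-h test against zeitgeber time (h). Grey points are libraries, lines join the means of 3 and bars are SD; Fabp7 falls from 590.4 CPM at ZT2 to 220.7 CPM at ZT14 and Fmo2 rises from 6.43 to 17.8 CPM.

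The test of any difference between the times named 13 genes, 11 of which had also passed the 24-h test. The other 2 were Alas2, the enzyme that starts haem synthesis in red cell precursors (edgeR adjusted p = 0.0220), and Emilin1, an elastic fibre glycoprotein (adjusted p = 0.0385). Alas2 was at 13.5 ± 0.68 CPM at ZT14 and 2.76 ± 0.62 CPM at ZT20. Emilin1 was at 6.30 ± 0.63 CPM at ZT2 and between 2.53 and 3.48 CPM at the other times. Emilin1 ends at 30921277 on chromosome 5, 153 bases before Khk starts on the same strand, and the 2 neighbours had opposite changes, so reads may have been divided between them. Most of the 13 calls were sensitive to leaving out 1 library, which also leaves fewer libraries to estimate the spread. Of the 12 such fits, Emilin1 was lost in 10, Alas2 and Dbp in 9, Ciart, Nr1d1 and Per3 in 7, Nr1d2 in 6, Slco1a4 in 5, Khk in 4 and Per2 in 2, and Arntl, Fabp7 and Fmo2 in 0. In these fits the amplitude was 1.05 to 1.16 for Dbp and 0.71 to 0.78 for Ciart. The log2 fold change was -2.48 to -2.20 for Alas2 (ZT20 against ZT14) and -1.53 to -1.19 for Emilin1 (ZT8 against ZT2). The adjusted p rose to 0.138 for Alas2 and 0.178 for Emilin1. The count was 4 without ZT8 replicate 1 or ZT20 replicate 3, 5 without ZT14 replicate 2, 6 without ZT2 replicate 1 or ZT8 replicate 2, 7 without ZT20 replicate 1 and 22 without ZT8 replicate 3. No gene passed the 12-h alternation in edgeR; the lowest adjusted p was 0.116, 1921 genes had an unadjusted p under 0.05, limma-trend named 0 and DESeq2 named 124. The 12-h count was 9 without ZT2 replicate 3 and 3 without ZT8 replicate 3.

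ZT14 and ZT2 are opposite times 12 h apart. Fmo2 rose 2.77-fold from ZT2 to ZT14, Fam107a 1.93-fold, Per2 1.85-fold, Khk 1.57-fold and Slco1a4 1.42-fold. Smaller rises were those of Galnt16, a glycosyltransferase, 1.32-fold, and Slc1a5, a neutral amino acid transporter, 1.28-fold. Fabp7 fell by 1.42 ± 0.08 on the log2 scale, Arntl fell by 1.24 ± 0.11, Spg21 fell by 0.47 ± 0.06, Sat1 fell by 0.41 ± 0.05 and Dbi fell by 0.36 ± 0.05 (SE). These were the 12 genes past the threshold, 7 higher and 5 lower, with 1339 at an unadjusted p under 0.05. All 12 had no overlap between the 3 libraries of each time, which chance gives for 10% of all genes. Because these 12 were selected on the same libraries, this is no added evidence. Galnt16 and Slc1a5 lost their calls whichever of the 12 libraries was left out, Sat1 in 10 of these fits, Spg21 in 8, Fam107a in 7, Dbi and Per2 in 6, Slco1a4 in 4 and Khk in 3, while Fmo2, Fabp7 and Arntl kept theirs in all 12. On the scale of approximate reads the split was 14 higher and 5 lower. Without ZT2 replicate 1 the count was 3, without ZT2 replicate 2 or ZT14 replicate 2 it was 4, without ZT2 replicate 3 or ZT14 replicate 3 it was 5, and without ZT20 replicate 3 or ZT8 replicate 1 it was 7, while the 6 libraries alone gave 6 and the fit without the libraries richest in muscle RNA gave 0.

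ZT20 and ZT8 are the other pair of opposite times and share no library with the first. Arntl rose 2.26-fold from ZT8 to ZT20. Dbp fell by 1.96 ± 0.24 on the log2 scale, Nr1d1 fell by 1.86 ± 0.19, Ciart, a repressor of the activators, fell by 1.34 ± 0.15, Per3 fell by 0.80 ± 0.11 and Nr1d2 fell by 0.70 ± 0.07 (SE). These 6 genes, 1 higher and 5 lower, were all clock genes, with edgeR adjusted p-values between 0.00843 and 0.0421, and 1364 genes had an unadjusted p under 0.05. With 1 library left out, Per3 lost its call in 10 of 12 fits, Dbp in 8, Ciart in 4, Nr1d1 and Nr1d2 in 2 and Arntl in 1. The count was 0 without ZT20 replicate 3, 2 without ZT8 replicate 1, 3 without ZT20 replicate 1 and 10 without ZT2 replicate 3, and the 6 libraries alone gave 2.

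Of the 4 contrasts between adjacent times, ZT20 against ZT14 had the most genes, 2 higher and 9 lower. Alas2 fell by 2.29 ± 0.24 and Hba-a1, an alpha globin whose near-identical copy Hba-a2 shares its reads, fell by 1.87 ± 0.24 on the log2 scale (SE), from 1286 ± 47.3 to 352.6 ± 70.8 CPM (SD, n = 3). Fmo2 fell by 1.23, Per2 by 1.13, Per3 by 0.83, Nr1d2 by 0.61, Bhlhe40 by 0.46 and Tef by 0.35, while Arntl rose 2.43-fold and Fabp7 rose 2.06-fold. Adamts1, a secreted metalloprotease chosen after its values were seen, fell by 0.67. Of the 12 fits without 1 library, Tef was lost in 11, Bhlhe40 and Hba-a1 in 10, Adamts1 in 9, Per3 in 6, Nr1d2 in 4 and Alas2 in 1, and Fmo2, Per2, Arntl and Fabp7 in 0. On the scale of approximate reads 4 genes were higher and 8 lower. From ZT2 to ZT8, 5 genes passed: Khk rose 1.64-fold and Slco1a4 rose 1.40-fold, Emilin1 fell by 1.31, Arntl fell by 1.14 and Fabp7 fell by 0.87; in the same 12 fits Emilin1 was lost in 10, Slco1a4 in 5, Khk in 3, Arntl in 1 and Fabp7 in 0. From ZT20 to ZT2, Khk alone passed and fell by 0.76 ± 0.08 (edgeR adjusted p = 0.0222), a call lost in 7 of the 12. Between ZT8 and ZT14 no gene passed in edgeR, with a lowest adjusted p of 0.0887, 1627 genes at an unadjusted p under 0.05, 0 genes in limma-trend and 103 genes in DESeq2. Leaving out 1 library moved the count of ZT20 against ZT14 between 4 (ZT20 replicate 3) and 17 (ZT2 replicate 3), with 5 without ZT14 replicate 2 or ZT20 replicate 1, 6 without ZT8 replicate 1 and 7 without ZT2 replicate 2 or ZT14 replicate 3; that of ZT8 against ZT2 moved between 1 (ZT2 replicate 1) and 10 (ZT8 replicate 3), with 3 without ZT2 replicate 2 or 3, ZT8 replicate 1 or ZT14 replicate 2. That of ZT2 against ZT20 was 11 without ZT2 replicate 3, 3 without ZT20 replicate 2, 2 without ZT8 replicate 3 and 0 without ZT2 replicate 1, ZT8 replicate 1 or 2, ZT14 replicate 3 or ZT20 replicate 1 or 3. That of ZT14 against ZT8 was 4 without ZT8 replicate 3, 2 without ZT20 replicate 1 and 1 without ZT14 replicate 1. Without the libraries richest in muscle RNA, ZT20 against ZT14 and ZT2 against ZT20 gave 0.

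Genes through which nociceptors detect stimuli, fire and signal were measured at 29 CPM or more, and of the 8 such genes reported here 0 passed the any-time or 24-h test in edgeR, limma-trend or DESeq2, with 0 at an unadjusted p under 0.05 in edgeR. Calca, the precursor of the peptide CGRP, was at 2800 ± 67.2 CPM at ZT2, 2723 ± 331.5 at ZT8, 2718 ± 10.9 at ZT14 and 2609 ± 250.0 at ZT20 (SD, n = 3 each). Scn10a, a sodium channel of nociceptors, ranged between 151.8 and 159.9 CPM, and Scn9a and Scn11a, channels of the same family, had 24-h amplitudes of 0.08 ± 0.04 and 0.05 ± 0.04 (SE). The heat-gated channel gene Trpv1 was at 131.3 ± 16.3 CPM at ZT2 and 115.6 ± 9.91 CPM at ZT14. For Scn9a, Scn10a, Scn11a, Trpv1, Trpa1, Calca, Tac1 and P2rx3, the 95% intervals of the log2 fold changes for ZT14 against ZT2 and for ZT20 against ZT8 all included 0. Together the intervals spanned -0.37 to 0.26.

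**Figure D3:**
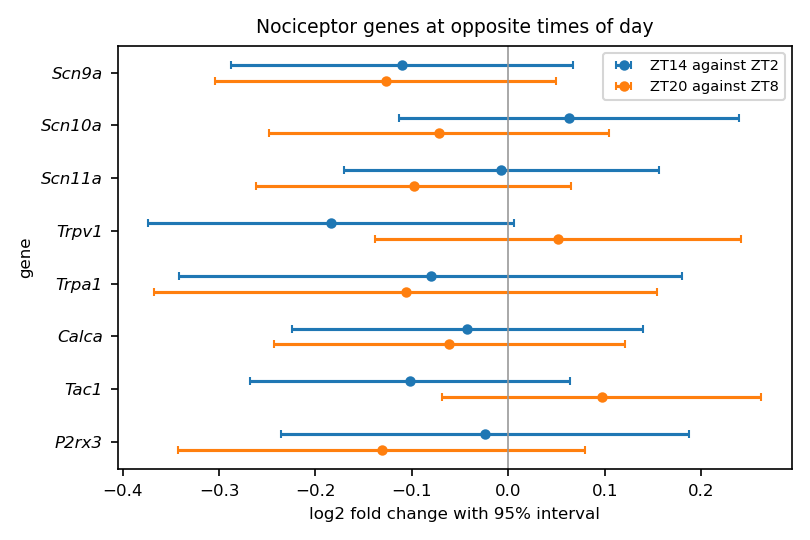
Log2 fold change (horizontal axis) of 8 nociceptor genes (vertical axis) for ZT14 against ZT2 and ZT20 against ZT8. Points are edgeR estimates and bars their 95% intervals, which lie between -0.37 and 0.26 and all include 0.

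Across the 12 neuronal and pain-related lists, 0 of 201 measured genes passed the any-time or the 24-h test of edgeR over all genes, and 9 and 6 had unadjusted p-values under 0.05. In limma-trend 0 passed either test. In DESeq2, Lpar1 passed the 24-h test, and Lpar1, Piezo2 and Mrgprx1 passed the any-time test. Piezo2, the mechanically gated channel of touch and proprioception, was at 109.3 ± 9.88 CPM at ZT2, 93.8 ± 13.9 at ZT8, 108.7 ± 10.8 at ZT14 and 80.5 ± 5.42 at ZT20 (SD, n = 3 each). Its adjusted any-time p in edgeR was 0.542. These lists held 14 sodium channel genes, 29 potassium and HCN channel genes, 15 calcium channel genes, 22 sensory transduction channels such as Piezo2, 15 neuropeptides such as Calcb and Adcyap1, 29 receptors for opioids, cannabinoids and inflammatory mediators, 19 cytokines and chemokines, 16 injury-induced genes, 16 pan-neuronal genes, and 12, 14 and 15 markers of peptidergic nociceptors, non-peptidergic nociceptors and pruriceptors, and myelinated or low-threshold neurons. Adjusted over the list alone, 1 gene passed the 24-h test, Lpar1, a lysophosphatidic acid receptor also expressed by Schwann cells, at 86.8 CPM at ZT2 and 73.2 to 76.0 CPM at the other times. None of the 12 lists passed camera in either contrast of opposite times.

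Of the 39 lists, 14 passed camera at the preset correlation for ZT14 against ZT2 and 7 for ZT20 against ZT8, but with an estimated correlation only the clock's repressor and output arm did so. That list rose from ZT2 to ZT14, with a median log2 fold change of 0.38, 11 of 12 members above 0 and a camera adjusted p of 3.4e-15 (adjusted p = 0.010 with an estimated correlation). It fell from ZT8 to ZT20, with a median of -0.53 and 0 of 12 members above 0 (adjusted p = 1.1e-23, and 0.00214 with an estimated correlation). The activator arm had a median of -0.12 for ZT14 against ZT2 (adjusted p = 0.513 with an estimated correlation) and of 0.19 for ZT20 against ZT8 (adjusted p = 0.228 with an estimated correlation, and 0.0208 by fry). The former median was -0.05 without ZT2 replicate 3 and -0.08 without ZT14 replicate 1, where the list did not pass, and -0.21 without ZT2 replicate 2; the latter was 0.11 without ZT20 replicate 3.

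Markers of neutrophils with marrow and of erythroid cells had their lowest scores in the 3 ZT20 libraries. Lcn2 belongs to both the neutrophil and the glucocorticoid list. Neutrophil and marrow genes had a median log2 fold change of -1.22 for ZT20 against ZT8, with 0 of 16 members above 0 (camera adjusted p = 1.5e-18, and adjusted p = 0.228 with an estimated correlation). S100a8, a calcium-binding protein abundant in neutrophils, was at 15.9 ± 2.08 CPM at ZT8 and 7.06 ± 1.33 CPM at ZT20 (SD, n = 3), and Camp, an antimicrobial peptide of granulocytes, at 6.33 ± 0.955 and 3.09 ± 0.938 CPM. Adjusted over the list alone, 11 of the 16 members passed the 24-h test, and 0 did over all genes in edgeR or limma-trend, with 12 at an unadjusted p under 0.05 and 4 past DESeq2. Erythroid genes had a median of -1.06 for ZT20 against ZT8, with 2 of 11 above 0 (camera adjusted p = 1.7e-07, and adjusted p = 0.262 with an estimated correlation), and 5 of 11 passed the 24-h test over the list alone. In the 12-h test over the list alone 11 of 16 neutrophil and 9 of 11 erythroid members passed, so the difference of ZT20 from the other times is not a 24-h pattern alone. The erythroid median was -0.56 in the table without haemoglobin, mitochondrial and muscle genes, which takes the globins out of the list. Haemoglobin took 0.0776% to 0.120% of the counts in the ZT20 libraries and 0.168% to 0.407% in the others. The markers of macrophages and of T and B cells did not pass camera; over the list alone, Cd163, a scavenger receptor of tissue macrophages, passed the 24-h test with 2.71 CPM at ZT14 and 1.27 CPM at ZT2.

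**Figure D4:**
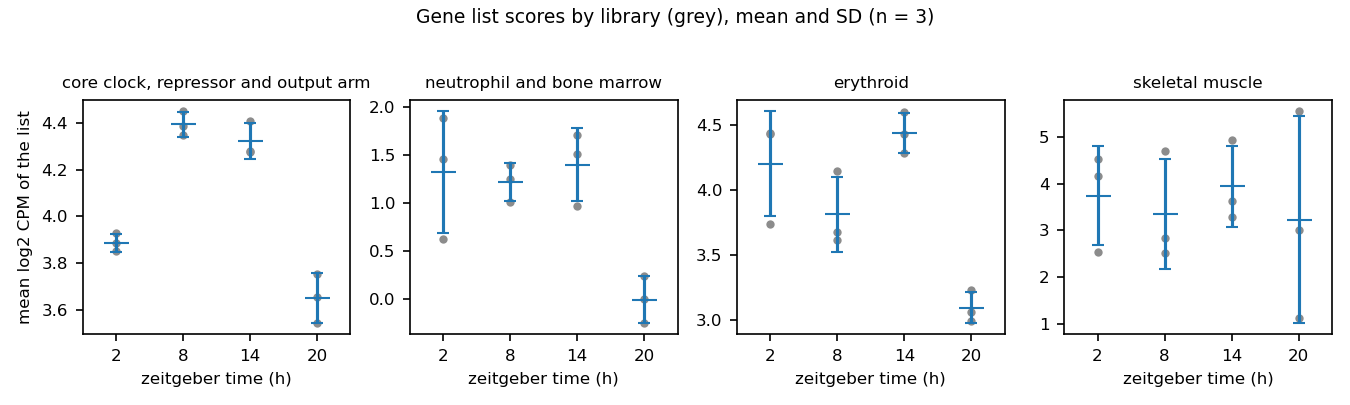
Mean log2 CPM of 4 gene lists (vertical axes, which do not start at 0) in each library (grey) at each zeitgeber time (h), with mean and SD of 3 as blue bars. The 3 ZT20 libraries are the lowest in the repressor arm, the neutrophil and marrow list and the erythroid list, while skeletal muscle scores spread from 1.14 to 5.55 within ZT20.

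Among stress and hormone lists, glucocorticoid-responsive genes had a median log2 fold change of 0.19 for ZT14 against ZT2, with 17 of 20 members above 0 (camera adjusted p = 6.9e-06, and adjusted p = 0.409 with an estimated correlation). Adjusted over the list alone, 9 of its 20 members passed the 24-h test, against 0 over all genes in edgeR or limma-trend, with 11 at an unadjusted p under 0.05 and 2 past DESeq2. Mt1, a metallothionein, was at 137.3 ± 10.6 CPM at ZT2 and 177.4 ± 15.6 CPM at ZT14. Plin4, a lipid droplet protein of fat and muscle, was at 0.338 and 0.969 CPM. The adipocyte list had a median of 0.96 in the same contrast with 11 of 11 members above 0 (adjusted p = 0.532 with an estimated correlation), and ZT14 replicate 1 had the highest adipocyte score of the 12 libraries, 1.9 log2 CPM. Without that library the adipocyte median was 0.21 and the list did not pass, and without ZT2 replicate 3 it was 0.64. The unfolded protein response had a median of -0.10 with 3 of 18 above 0 (adjusted p = 0.409 with an estimated correlation), with Hsp90b1 past the 24-h test over the list alone, and heat shock genes had a median of -0.07 with 4 of 18 above 0 (adjusted p = 0.575 with an estimated correlation). Heat shock did not pass without ZT2 replicate 1 or ZT14 replicate 2, with medians of -0.05 in both. Clock outputs of many tissues had a median of 0.15, which was -0.0046 without the libraries richest in muscle RNA (adjusted p = 0.409 with an estimated correlation), and 3 of 19 passed the 24-h test over the list alone. Their median was 0.05 without ZT2 replicate 2, where the list did not pass, 0.03 without ZT14 replicate 1, 0.08 without ZT2 replicate 3 and 0.09 without ZT14 replicate 3.

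Vessel and support cell lists were also higher at ZT14 than at ZT2 at the preset correlation only. Their medians were 0.16 for endothelium, 0.27 for smooth muscle and pericytes, 0.13 for fibroblasts and 0.11 for myelinating Schwann cells (adjusted p = 0.409, 0.532, 0.773 and 0.575 with an estimated correlation). Without ZT14 replicate 1 the smooth muscle and pericyte median was 0.04 and the fibroblast median 0.12, and without ZT2 replicate 3 the fibroblast median was 0.07; these lists did not pass there. In the endothelial list 4 of 14 members passed the 24-h test over the list alone, and 1, Slco1a4, over all genes. Ly6c1, an endothelial surface protein, was at 69.0 CPM at ZT2 and 98.6 CPM at ZT14. Cholesterol synthesis genes had a median of 0.04, erythroid genes of 0.13 and interferon-stimulated genes of -0.35 in this contrast (adjusted p = 0.532, 0.641 and 0.575 with an estimated correlation). The erythroid list did not pass without ZT2 replicate 3, with a median of 0.01, ZT8 replicate 3 (0.12) or ZT14 replicate 2 (0.10), and its median was 0.21 without ZT2 replicate 1 or ZT14 replicate 3 and 0.34 without ZT2 replicate 2. The interferon median was -0.14 without ZT2 replicate 2, where the list did not pass. For ZT20 against ZT8 the median was 0.15 for myelinating Schwann cells, -0.36 for interferon-stimulated genes and -0.21 for cell cycle genes (adjusted p = 0.743, 0.743 and 0.228 with an estimated correlation). The Schwann cell median was 0.07 without ZT8 replicate 2, where the list did not pass, and 0.23 without ZT8 replicate 3. The interferon median was -0.23 without ZT20 replicate 1 and -0.60 without ZT20 replicate 2. The cell cycle median was -0.10 without ZT8 replicate 3, where the list did not pass, -0.34 without ZT8 replicate 1, -0.13 without ZT20 replicate 1 and -0.14 without ZT20 replicate 2. Without the library richest in muscle RNA at each time, the activator arm, clock outputs, adipocyte, smooth muscle and interferon lists did not pass for ZT14 against ZT2, nor did the interferon and cell cycle lists for ZT20 against ZT8. The erythroid list did not pass for ZT14 against ZT2 without haemoglobin, mitochondrial and muscle genes or with 1 surrogate variable, nor the cell cycle list for ZT20 against ZT8 with CPM 1 in 6 libraries. The satellite glia list passed camera in neither contrast, and 2 of its 12 members passed the 24-h test over the list alone, Fabp7 and Glul, the glutamine synthetase. Camera at the preset correlation called neither contrast for cold-inducible proteins, immediate early genes, skeletal muscle, bone and cartilage, spinal cord, the respiratory chain, ribosomal proteins or mitochondrially encoded genes. In edgeR and limma-trend 0 of their members passed the 24-h or any-time test over all genes, with 1, 3, 0, 1, 0, 2, 1 and 0 members in this order at an unadjusted 24-h p under 0.05 in edgeR. Over the list alone 7 immediate early and 2 cold-inducible genes passed the any-time test of edgeR, and 0 members of the 8 lists passed the 24-h test. DESeq2 named Fos, Dusp1, Egr3, Junb, Srsf5 and Ndufc1 in the any-time test and Rps18 in the 24-h test. Of these, only Junb lies outside the naming rule and was chosen after its values were seen. In 21 of the uncalled tests the median, mean or direction of camera differed in sign, as for skeletal muscle in ZT20 against ZT8, with a median of 0.84 and a camera direction of lower.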

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

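The tests on assembled loci, on whole blood, on library size, on Fabp7, and on the glucocorticoid list were chosen after the results they measure were seen; the test on bone marrow was not.

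The loci that StringTie assembled without an Ensembl ID took a median of 0.224% of a library's total and were left out of the comparisons, so their counts lie outside the main measurement. When the 348 loci were added to the table, 290 were tested, 0 passed the edgeR any-time or 24-h test, 32 had an unadjusted any-time p under 0.05, and the lowest adjusted p was 0.441.

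Neutrophil, marrow and erythroid transcripts had a median log2 fold change of -1.18 for ZT20 against ZT8 over 27 members. An effect of library size or normalization shared by genes of the same mean level is argued against. The lowest median of 10000 lists of other genes matched on mean level was -0.15. Under RLE size factors and approximate reads the neutrophil medians were -1.22 and -1.18 and the erythroid medians -1.06 and -1.08. Without haemoglobin, mitochondrial and muscle genes, which takes the globins out of the erythroid list, the 2 medians were -1.22 and -0.56. These scalings could move the medians little, so they decide little. Bone marrow carried over in dissection stays open. The neutrophil and erythroid scores, which share no gene, deviated together within times with r = 0.68 (Spearman's rho 0.47, 12 libraries). The exact permutation p-values were 0.104 and 0.218 (0.156 and 0.326 adjusted over 3 relations), and r was 0.49 without the 2 libraries farthest from the median. A varying amount of blood could give such a correlation too, so it does not point to marrow. In the same family, the neutrophil score had r = 0.69 with the cell cycle score (exact permutation p = 0.0355, adjusted 0.106) and r = 0.0841 with the T and B cell score (exact permutation p = 0.822, adjusted 0.822). Less whole blood could not be tested well, because the T and B cell score differed by -0.10 ± 0.45 (SE) against -0.72 ± 0.18 for the erythroid score, and a daily change in circulating cells and a batch of collection, which follows time of day here, stay open as well.

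Fabp7 was lower at ZT14 than at ZT2 by 1.42 on the log2 scale. A smaller share of satellite glia is argued against, because the other 11 markers of these cells had a median log2 fold change of 0.0403, with quartiles of -0.07 and 0.11. The value nearest to 0 over RLE size factors, approximate reads, DESeq2 and the table without haemoglobin, mitochondrial and muscle genes was -1.42. This decides little about the normalization, because for 1 gene these settings differ almost only in the factor of each library. Those factors lay between 0.97 and 1.02 in the main fit, so a large move was barely possible. A change of Fabp7 itself with time of day remains as a hypothesis; a collection batch cannot be told apart from it.

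Glucocorticoid-responsive genes had a higher median at ZT14 than at ZT2. A single library is argued against as the source of the median of 0.19. Over the 23 other settings that tested the list, each library left out in turn among them, the median ranged from 0.16 to 0.23. Leaving out ZT14 replicate 1, the test chosen for this, decides little by itself. That library had the lowest score of the list at ZT14, 4.32 log2 CPM against 4.38 and 4.63. Without it the median was 0.22, and 0.17 to 0.34 when another library was also left out. Fat carried over with the ganglia stays open: with the adipocyte score as a covariate the median was 0.26, but it ranged from 0.13 to 0.31 when single libraries were left out. The daily rhythm of corticosterone is an untested biological alternative, and the number of list calls itself could not be told from chance, as 26 of 100 groupings gave as many.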

How the results depend on the processing

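The settings named in the methods as chosen after seeing the data are approximate reads, limma-trend, protein-coding genes only, both muscle settings and the assembled loci. Over the settings that gave them a value, no called fold change of a named gene changed sign and no called list changed the direction of its test; the median of the clock outputs list for ZT14 against ZT2 was -0.0046 without the libraries richest in muscle RNA, where it was not called. The values besides the main counts were those of named genes and lists, with counts of list members and of higher and lower genes. With 1 library left out, 4324 of these kept their side of the threshold or, for counts, stayed within 1.5 times. A further 343 lost it, 9 gained it and 64 counts moved by more. Under the other settings these numbers were 4713, 148, 106 and 60. Of the main counts, 66 stayed and 54 moved with 1 library left out, and 94 stayed and 42 moved under the other settings. The median log2 fold change of all genes stayed within 0.0091 of 0. RLE size factors, limma-trend, the assembled loci and the table without haemoglobin, mitochondrial and muscle genes changed none of the counts below by over 1.5 times. All 17 genes of the 24-h test remained under RLE size factors, DESeq2, no filter, limma-trend and approximate reads.

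The counts below are given in the order any-time, 24-h, 12-h, ZT14 against ZT2, ZT20 against ZT8, ZT8 against ZT2, ZT14 against ZT8, ZT20 against ZT14 and ZT2 against ZT20, where edgeR with all libraries gave 13, 17, 0, 12, 6, 5, 0, 11 and 1. DESeq2 gave 292, 162, 124, 106, 68, 82, 103, 112 and 80. In the simulated data 45.6% of its any-time calls and 39.8% of its 24-h calls were false, against 3.70% and 4.30% for edgeR. Those data were drawn with dispersions from edgeR, which may favour edgeR. The shares also depend on the 200 genes changed there, so they do not give the false share of the real DESeq2 calls. For the other settings only counts that moved by over 1.5 times are given. Without a filter, ZT14 against ZT8 gave 1. With CPM 1 in 6 libraries, any-time gave 21 and ZT14 against ZT8 gave 1, with fewer genes tested. With 1 surrogate variable, any-time gave 24, 12-h gave 3, ZT14 against ZT2 gave 19, ZT14 against ZT8 gave 4, ZT20 against ZT14 gave 18 and ZT2 against ZT20 gave 2. The 6 libraries alone gave 6 for ZT14 against ZT2, 2 for ZT20 against ZT8, 0 for ZT8 against ZT2, 4 for ZT14 against ZT8 and 0 for ZT2 against ZT20, with fewer libraries to estimate the spread. Approximate reads gave 5 for 12-h, 19 for ZT14 against ZT2 and 1 for ZT14 against ZT8. Protein-coding genes alone gave 20 for any-time and 1 for ZT14 against ZT8. Without the library richest in muscle RNA at each time, any-time gave 8, 24-h gave 4, and ZT14 against ZT2, ZT20 against ZT14 and ZT2 against ZT20 gave 0, with 8 libraries left. With the muscle score as a covariate, ZT14 against ZT8 gave 3 and ZT2 against ZT20 gave 3. Unless a reason is named, the cause was not tested.

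With the replicate block, any-time gave 7, 24-h gave 4, ZT14 against ZT2 gave 5, ZT20 against ZT8 gave 2 and ZT8 against ZT2 gave 3. The numbers did not pair the libraries: deviations from the time means correlated with r of -0.06 to 0.08 over the 18 pairs of the same number, none above 0.1, and 4 of 12 libraries were closest to their own number, so the block fit spends degrees of freedom on a factor the data do not show.

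Of the gene lists, 21 passed camera at the preset correlation over both contrasts, 2 with an estimated correlation and 3 by fry.

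Leaving out 1 library in turn, the counts ranged from 4 to 22 for any-time, 5 to 17 for 24-h, 0 to 9 for 12-h, 3 to 13 for ZT14 against ZT2, 0 to 10 for ZT20 against ZT8, 1 to 10 for ZT8 against ZT2, 0 to 4 for ZT14 against ZT8, 4 to 17 for ZT20 against ZT14, 0 to 11 for ZT2 against ZT20 and 19 to 24 for the lists.

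Random groupings bear on chance. For any-time, 4 of 100 groupings of the 12 libraries, the real one included, gave 13 or more genes (highest other 19). For 24-h, 2 of 100 gave 17 or more (highest other 51). Chance is thus an unlikely source of both counts past the threshold, but it is not excluded. At an unadjusted p under 0.05, 15 and 20 of 100 gave as many genes as the real 1598 and 1342, so chance is not excluded for those numbers. The groupings of 51 and 19 calls divided the libraries by muscle RNA, with 68.7% and 66.5% of the variance of the muscle score between their groups against 5.81% for the real times. For 12-h the real count was 0, which all 100 must reach, so the groupings decide nothing (highest other 244); the grouping with 244 put the 4 libraries richest in muscle RNA on 1 side. For the lists, 26 of 100 gave 21 or more (highest other 31), and chance is not excluded; with an estimated correlation the highest other was 0 against 2. For each pair of times there are 10 splits, too few for a share under 0.05: as many genes as the real split were given by 1 for ZT14 against ZT2 (12, highest other 2), 1 for ZT20 against ZT8 (6, other 1), 1 for ZT8 against ZT2 (5, other 1), 10 for ZT14 against ZT8 (0, which each split must reach, other 2), 1 for ZT20 against ZT14 (11, other 1) and 3 for ZT2 against ZT20 (1, other 2).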

Other observations

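The following was looked at only after the values were seen. Immediate early genes, which respond within minutes to activity or handling, tended to be higher at ZT2 and ZT14 than at ZT8 and ZT20: the median log2 difference was 0.22, 18 of 20 members lay above 0, and 7 passed the 12-h test adjusted over the list alone (Klf4, Fos, Dusp1, Egr3, Egr1, Jun and Junb), with 0 over all genes in edgeR or limma-trend. Fos was at 7.63 ± 0.97 and 7.71 ± 1.95 CPM at ZT2 and ZT14, and at 5.08 ± 0.69 and 4.83 ± 0.39 CPM at ZT8 and ZT20 (SD, n = 3). Heat shock genes went the same way, with a median of 0.09 and 17 of 18 members above 0, Hspa1a, Hspa1b and Dnajb1 among the 5 that passed over the list alone. Camera with an estimated correlation gave an adjusted p of 0.0975 for the former list and 0.304 for the latter. Blood and marrow markers had larger differences in the same direction: the erythroid median was 1.08, with 11 of 11 members above 0 and 9 past the 12-h test over the list alone (adjusted p = 0.0975 with an estimated correlation), and the neutrophil and marrow median was 0.91, with 16 of 16 above 0 and 11 past it (adjusted p = 0.305). The scores of these lists were lowest at ZT20: in the order ZT2, ZT8, ZT14 and ZT20 the neutrophil means were 1.33, 1.22, 1.40 and -0.0026 log2 CPM and the erythroid means 4.20, 3.81, 4.44 and 3.09 log2 CPM. The neutrophil mean at ZT8 was level with ZT2 and ZT14, so its difference came from ZT20, whereas the immediate early means were 3.06, 2.78, 3.03 and 2.83 log2 CPM. For the 12-h test DESeq2 named 124 genes over all genes, 1921 genes had an unadjusted p under 0.05 in edgeR, and 12 of 100 groupings of the libraries gave as many.

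Il31ra, a receptor of itch neurons, was at 78.9 CPM in ZT2 replicate 2 and between 8.51 and 13.4 CPM in the other 11 libraries. It was 1 of 4 genes with a level of 10 CPM or more in 1 library and at least 5 times that of each other library; Gemin7 stood out in ZT8 replicate 1 with 15.1 CPM against at most 1.83. Xist, which is transcribed from the inactive X chromosome of females, was at 0.0181 CPM or below in each library and Ddx3y, a gene of the Y chromosome, at 14.7 CPM or above, with all libraries labelled male.

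A hypothesis chosen after the values were seen was that excitability genes carry small 24-h changes that single-gene tests miss. Of 95 genes of the sodium, potassium and calcium channel, transduction and neuropeptide lists, 4 had an unadjusted 24-h p under 0.05 (Cacnb3, Tmem120a, Calcb and Adcyap1), against a median of 5 in 10000 lists of other genes matched on mean level. The median amplitude was 0.06, above that of 99.2% of the matched lists, whose median was 0.05, while the median p was 0.463 against 0.470, and 44.7% of the matched lists had a lower one. An amplitude is above 0 without any rhythm and grows with the spread between libraries, on which the lists were not matched. The higher median amplitude is therefore no evidence of 24-h changes. The count of 4 genes and the median p were close to those of the matched lists, and the question stays open.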
